A study of Arabidopsis thaliana with 9 samples.

How the data were processed

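The series holds 9 Arabidopsis thaliana samples, and the 4 RNA-seq libraries of 6-day seedlings are analysed here. Of these, 2 are wild type (Columbia-0) and 2 carry the label of an hd2b hd2c double mutant. The other 5 samples, from 2-week leaves, are not analysed here: chromatin immunoprecipitation of acetylated H4K16 in wild type and hd2c, chromatin immunoprecipitation of FLAG-tagged HD2C, and RNA immunoprecipitation with FLAG beads in wild type and in the tagged line. Each table column was matched to its library by the genotype abbreviation and number in its header. The labels do not say whether the 2 libraries of a group came from separately grown plants, so p-values measure only the spread between these samples, which may be technical.

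The deposited table gives FPKM (fragments scaled to transcript length and to the mapped fragments) for each locus and library, per the file headers. RNA libraries were made with a TruSeq RNA kit, per the labels' protocols. The genome build TAIR10 and the tools TopHat, Bowtie2 and bedtools appear in the submitters' processing notes, with no role given. The program that computed FPKM, the gene models behind it, the use of strand and the treatment of reads shared between copies are not given in the sources used here. The table has no fragment counts, so sequencing depth is unknown and no counting interval is given.

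A count model had been chosen for the case that the table held counts. Because it holds FPKM, the model written beforehand for normalized values was used: limma (version 3.58.1 in R 4.3.3) on log2(FPKM + 1), with a mean-variance trend and robust empirical Bayes moderation. Loci with at least 1 FPKM in at least 2 of the 4 libraries were tested, which left 19917 of 33278 loci. Genotype was the only term. P-values were two-sided and adjusted by Benjamini-Hochberg over the tested loci, with a threshold of 0.05. Log2 changes are labelled mutant minus wild type on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. Folds in the text are ratios of group means of FPKM. Every adjusted p of a gene comes from this limma fit unless another setting is named.

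Gene lists, the naming rule, the tests and most alternative settings were fixed before the data were examined. The lists were tested with camera (limma) with its preset inter-gene correlation of 0.01, adjusted over the 22 lists with at least 5 tested members. Camera was also run with a correlation estimated from the 4 libraries, which raised p even where the estimate was below the preset. In that form its degrees of freedom come from the residuals of the 4 libraries, not from the number of genes. A large shift may therefore fail it. Lists of plastid and mitochondrial genome genes had been planned, and the table has no such loci. Planned lists of transposable element genes and organellar ribosomal proteins are not analysed here. One planned ribosomal protein locus was dropped because the reference gives it the symbol of a receptor kinase. Named genes are the 4 HD2 genes, the 8 largest rises and 8 largest falls, and up to 3 members per list with the smallest p. The largest changes had to pass the threshold, have a mean of at least 1 FPKM, and have both labelled mutant libraries on the same side of both wild-type libraries. Members of lists of 8 or fewer genes were also eligible. The text describes only part of the genes that meet this rule. In addition, 1 gene is not reported here, and it stays in the fit and the list tests. Any other gene is said to have been chosen after its values were seen.

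Symbols, locus types, gene order and the span of each gene came from a RefSeq gene table of assembly TAIR10.1, to which 32820 loci (98.6%) matched. The assembly differs in name from the authors' build, so no coordinates are printed, and gene span is used only as an approximate measure of length. List names follow common usage, and 226 of them are not among the symbols or synonyms of that table, so locus identifiers are printed beside names that differ.

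Alternatives covered quantile normalization, other filters on low values, other pseudocounts, a replicate block, rescaling without rRNA loci, a stricter threshold, each library left out in turn, and other list tests. Leaving out a library leaves 1 library in its group, so the spread then comes only from the 2 libraries of the other genotype, and calls gained or lost that way show dependence on a library rather than evidence for or against a change. Added after the data were seen were removal of the trend on gene span, alone and with the block, and scaling of each column to the same sum. The fit was tested on simulated data for the 19917 loci of this comparison with 200 changed. It recovered 82% of genes changed by a log2 of 1 and 100% of those changed by a log2 of 2, and 8 of its 192 calls were unchanged genes. A simulated list of 50 genes shifted by 0.5 gave a camera p of 8.52e-38, and 1 of 20 unshifted lists fell under 0.05. The simulated genes varied independently, so this does not show how camera behaves on lists whose genes vary together. The simulated noise followed the variances of the limma fit itself, with no trend on gene span and no difference between libraries beyond genotype. Changes were placed only in genes above a minimum mean level. The recovery and error counts therefore hold for that model and not for the real values.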

Results

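Gene expression was measured by RNA-seq in 6-day seedlings of wild-type Arabidopsis and of plants labelled as hd2b hd2c double mutants, with 2 libraries per genotype. HD2B and HD2C belong to the HD2 family of plant-specific histone deacetylases, which are largely nucleolar proteins. The comparison asks which transcripts change when both genes are mutated. FPKM values summed to 988524 and 992451 in the wild-type libraries and to 956002 and 1105981 in the labelled mutant libraries, and 19537 to 19767 loci reached 1 FPKM in each. Correlations of log2(FPKM + 1) across tested loci were 0.984 and 0.984 within genotypes and 0.971 to 0.978 between them. Loci are not independent replicates.

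The low values of the table differed in structure between libraries. Among loci above 0 in a library pair and under 1 FPKM in all 4 libraries, the ratio of wild-type library 2 to labelled mutant library 2 took fixed steps. Of 3370 such loci, 54.9% lay within 0.2% of 1.046 times a ratio of whole numbers up to 4, against 1.27% to 2.35% in the other 5 pairings. The low values of the libraries numbered 2 therefore shared a structure that those numbered 1 did not, and its cause was not tested. Medians of the lists below are for this reason also given for each number. Fold changes also fell with gene span: the median log2 change was 0.15 in the 1986 tested genes of shortest span (median 849 bp) and −0.17 in the 1985 of longest span (median 5690 bp). The cause of this trend was not tested. An rRNA locus, AT3G41768, stood at 110 and 2033 FPKM in wild type and at 108 and 466 FPKM in the labelled mutants. AT2G01021, a short locus that the reference lists as protein coding, stood at 6823 and 1814 FPKM in wild type and at 1850 and 12144 in the labelled mutants, of which library 2 also had the largest FPKM sum.

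HD2B was strongly reduced in the labelled mutant libraries and HD2C was not. HD2B (AT5G22650) averaged 164 ± 37.4 FPKM in wild type and 24.3 ± 0.0503 in the labelled mutants (SD, n = 2 each), 6.76-fold lower, with a log2 change of −2.69 (SE 0.17, adjusted p = 3.62e-04). HD2C (AT5G03740) stood at 56.1 and 63.9 FPKM in wild type and 74.7 and 55.8 in the labelled mutants, a log2 change of 0.11 (SE 0.16, adjusted p = 0.791). FPKM covers the whole locus and the labels do not give the insertion site, so the HD2C value does not show whether a full transcript was made. Because HD2C was not lower, the libraries are called labelled mutants throughout, and every direction below rests on the labels and on HD2B. The other 2 family members were higher in both labelled mutant libraries. HD2D (HDT4, AT2G27840) rose 1.68-fold, from 48.3 ± 3.56 to 81.1 ± 7.38 FPKM (log2 0.73, SE 0.13, adjusted p = 0.0476). HD2A (HDA3, AT3G44750) stood at 48.9 and 69.9 FPKM in wild type and at 95.3 and 124 in the labelled mutants, and did not pass the threshold (log2 0.88, SE 0.20, adjusted p = 0.109). The HD2D call ended without wild-type library 1 (adjusted p = 0.195), without labelled mutant library 2 (0.0624), with no filter on low values (0.182) and with a pseudocount of 0.1 (0.0514). HD2A passed without wild-type library 2 (adjusted p = 0.00474) and when columns were rescaled without rRNA loci (0.0173).

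**Figure D1:**
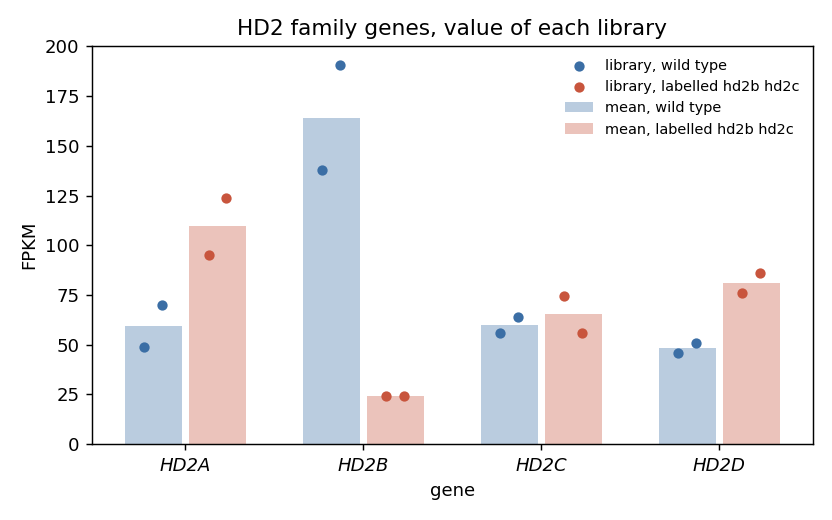
FPKM of the 4 HD2 family genes; points are libraries and bars are means of the 2 libraries per genotype. HD2B falls from 138 and 191 FPKM in wild type to 24.2 and 24.3 in the labelled mutants, while the HD2C values of both genotypes overlap between 55.8 and 74.7.

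Across all tested loci, 121 were higher and 110 lower in the labelled mutant libraries, and 76 of the higher and 80 of the lower changed at least 2-fold on the log2(FPKM + 1) scale. The largest falls included TAT3, SAG13, NATA1 and PR1. TAT3, a jasmonate-responsive tyrosine aminotransferase, fell 12.6-fold (log2 −3.18, SE 0.22, adjusted p = 0.00146). SAG13, a senescence-associated dehydrogenase, fell 9.79-fold (log2 −2.79, SE 0.14), and NATA1, an acetyltransferase, fell 9.20-fold (log2 −2.77, SE 0.16). PR1, the standard marker of the salicylic acid response, fell from 9.56 and 7.54 FPKM to 0.146 and 0.162. BSMT1, which methylates salicylic and benzoic acid, fell from 6.61 and 7.56 to 0.0407 and 0.110 FPKM. ELI3-2, an alcohol dehydrogenase induced by pathogens, fell from 8.85 and 11.6 to 0.175 and 0.367 FPKM. The microRNA locus MIR472 (13.7 and 13.3 FPKM in wild type) and the locus AT2G20784 (11.1 and 8.21) were listed at 0 in both labelled mutants.

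The largest rises included seed albumins and a transcription factor. SESA1, SESA2 and SESA4 encode 2S albumins, which store nitrogen in seeds. SESA1 was listed at 0 and 0.0946 FPKM in wild type and stood at 16.2 and 32.1 in the labelled mutants, SESA2 at 0 and 0.355 against 22.3 and 20.8, and SESA4 at 0 and 0.0976 against 8.71 and 21.7. NAC044, a NAC transcription factor that acts in DNA damage signalling, rose 11.7-fold, from 1.16 ± 0.333 to 13.6 ± 1.65 FPKM (log2 2.76, SE 0.17, adjusted p = 3.52e-04). AT3G05950 rose 9.52-fold (log2 2.76, SE 0.18, adjusted p = 6.07e-04). AT1G68250 rose from 0.0977 and 0.380 to 7.93 and 10.9 FPKM (adjusted p = 5.20e-04). AT5G14560 was listed at 0 in both wild-type libraries and stood at 47.9 and 96.0 FPKM in the labelled mutants. MIR164b, whose microRNA targets NAC genes of organ boundaries, was listed at 0 in both wild-type libraries and at 11.4 and 10.4 FPKM in the labelled mutants.

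**Figure D2:**
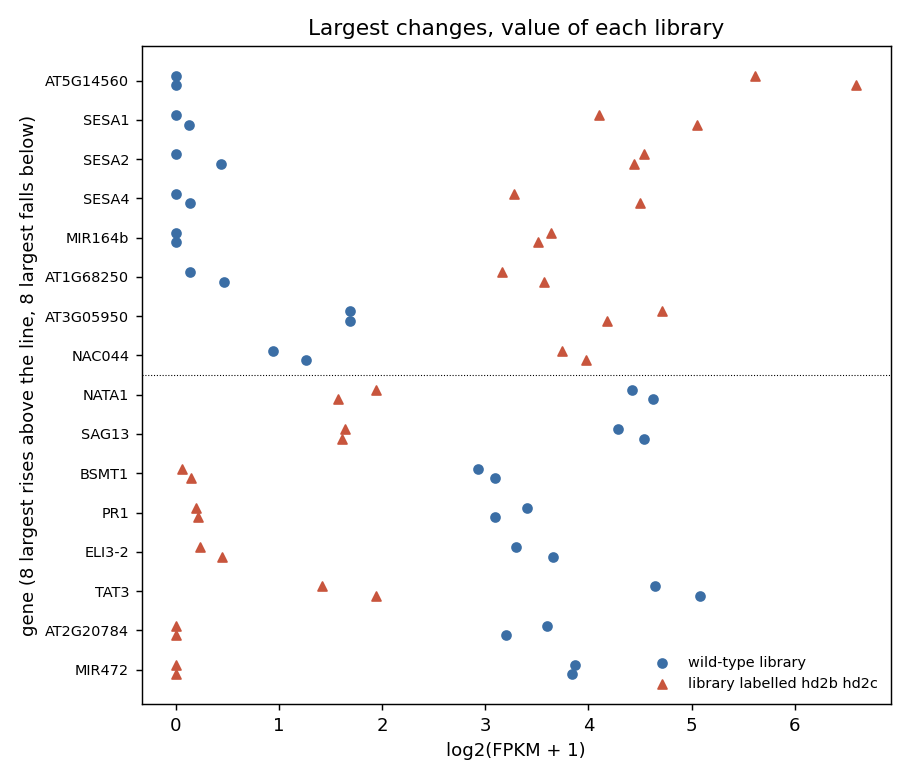
The 8 largest rises and 8 largest falls that met the naming rule, as log2(FPKM + 1) in each of the 4 libraries. AT5G14560 and MIR164b lie at 0 in both wild-type libraries, and MIR472 and AT2G20784 lie at 0 in both labelled mutant libraries.

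An exact 0 in this table can be a failed estimate: 62 loci were listed at 0 in one library of a genotype and at 10 FPKM or more in the other, with a median span of 153 bp against 2356 bp for tested loci, and 8 of the ribosomal protein loci were listed at 0 in at least 1 library. The calls of AT5G14560, SESA1 and SESA4 ended without wild-type library 1 (adjusted p = 0.408, 0.142 and 0.664) and without wild-type library 2 (0.251, 0.0947 and 0.504), and that of SESA2 with a pseudocount of 0.1 (0.0760). The number of calls depended on the settings. Of 33 named genes called outside the HD2 family, 18 lost the call with no filter on low values. Higher and lower loci numbered 19 and 20 with no filter on low values, 332 and 284 with columns rescaled without rRNA loci, and 60 and 80 with the trend on gene span removed. Columns scaled to equal sums with all loci kept gave 320 and 274. Higher loci numbered 390 without wild-type library 2 and 234 without labelled mutant library 1. At an unadjusted p under 0.05 there were 3420 loci (17.2%), and groups did not overlap in 49.4% of loci, where chance gives 33.3%.

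Genes for the ribosome were higher in the labelled mutant libraries almost without exception. Of 208 cytosolic ribosomal protein genes tested, 207 had a log2 change above 0, with a median of 0.51 (quartiles 0.45 and 0.57). Medians were 0.42 between the libraries numbered 1 and 0.60 between those numbered 2. Over all genes tested 5 rose and 1 fell, and adjusted over the list alone 175 rose and 1 fell. Some of the risers were weakly expressed copies. RPS23A (AT3G09680) rose 3.46-fold, from 2.46 ± 0.0316 to 8.52 ± 0.546 FPKM (log2 1.46, SE 0.14, adjusted p = 0.00371), and RPP0A (AT2G40010) rose 2.68-fold (log2 1.34, SE 0.14, adjusted p = 0.00599). The faller was RPL3B, 1 of the copies of the RPL3 gene, which dropped 2.17-fold from 42.2 ± 4.80 to 19.5 ± 0.420 FPKM (log2 −1.07, SE 0.12, adjusted p = 0.00938). The camera test gave an adjusted p of 1.84e-43 for the list, and an adjusted p = 0.390 with an estimated correlation. How reads shared between ribosomal protein copies were counted is not given, so single copies are uncertain.

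The same direction held for factors that assemble ribosomes. Of 50 ribosome biogenesis genes, 47 lay above 0 (median 0.33, by number 0.42 and 0.27) and 3 rose, 14 adjusted over the list alone (camera adjusted p = 2.76e-12, adjusted p = 0.420 with an estimated correlation). The risers were FIB2 (fibrillarin, 1.86-fold, adjusted p = 0.0455), NOP10 of the pseudouridylation complex (1.72-fold, adjusted p = 0.0464) and the nucleolin gene NUC-L2 (AT3G18610, 2.63-fold, adjusted p = 0.0481). These calls lay near the threshold: without wild-type library 1 their adjusted p were 0.154, 0.312 and 0.0560, and without labelled mutant library 2 FIB2 and NUC-L2 stood at 0.0726 and 0.0598. NOP10 no longer passed without wild-type library 2 (adjusted p = 0.0813), nor NUC-L2 without labelled mutant library 1 (0.0930), and none of the 3 passed with the trend on gene span removed. Their log2 changes with the trend removed were 0.87 for FIB2, 0.66 for NOP10 and 1.03 for NUC-L2, against 0.89, 0.78 and 0.95 before. Of 71 snoRNA loci only 13 passed the filter on low values and were tested, so the list stands for few of them. Among these 13, 12 lay above 0 (median 0.34, by number 0.26 and 0.52, camera adjusted p = 0.00408, adjusted p = 0.390 with an estimated correlation). Their mean log2 change was 1.15 and the upper quartile 1.3, so part of the loci changed far more than the rest. With the trend on gene span removed the snoRNA median was 0.19. One snoRNA, AT4G39364, rose 2.06-fold (adjusted p = 0.0476, but 0.115 without wild-type library 2, 0.157 with quantile normalization and 0.136 with columns rescaled without rRNA loci, the call also ending at a log2 of 0.88 with the trend on gene span removed), and it was the 1 riser adjusted over the list alone; U3D (AT5G54075, 3.76 ± 1.35 against 7.11 ± 1.85 FPKM) and AT1G03502 did not pass, U3D doing so without wild-type library 2 (adjusted p = 0.00631). All 29 cell division genes lay above 0 (median 0.27, by number 0.30 and 0.30, camera adjusted p = 5.90e-09, adjusted p = 0.390 with an estimated correlation). None passed over all genes and 3 did adjusted over the list alone; 3420 loci passed an unadjusted 0.05 in the same limma fit. The smallest p values belonged to PCNA1, the replication clamp (1.48-fold, adjusted p = 0.0977), and the mitotic cyclins CYCB1;1 (1.59-fold, adjusted p = 0.106) and CYCB1;2 (AT5G06150, 1.39-fold, adjusted p = 0.123).

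Iron deficiency genes were higher together. Of 18 tested, all lay above 0 with a median log2 change of 1.07 (1.19 and 0.75 by replicate number). Of these 6 rose over all genes and 13 adjusted over the list alone (camera adjusted p = 2.53e-14, adjusted p = 0.390 with an estimated correlation). BHLH100, a transcription factor of the iron deficiency response, rose 2.93-fold from 60.7 and 85.5 to 230 and 198 FPKM (log2 1.55, SE 0.18, adjusted p = 0.0103, but 0.125 with no filter on low values). The iron-signalling peptide genes IMA1 (AT1G47400) and IMA2 (AT1G47395) rose 2.33-fold and 2.32-fold (adjusted p = 0.0113 and 0.0128); IMA2 had an adjusted p of 0.0866 without wild-type library 1. The other 3 risers, named after their values were seen, were bHLH38, bHLH39 and the root iron transporter gene IRT1.

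The salicylic acid, jasmonate, and abscisic acid and cold lists were lower with the preset correlation of camera. In the salicylic acid and immunity list, 14 of 17 lay below 0 (median −0.40, by number −0.51 and −0.45), 2 fell over all genes and 8 adjusted over the list alone. The camera adjusted p was 6.10e-07, and 0.390 with an estimated correlation. Beside PR1, WRKY70, a transcription factor of salicylic acid signalling, fell 2.46-fold (log2 −1.16, SE 0.20, adjusted p = 0.0429). The WRKY70 call ended with quantile normalization (adjusted p = 0.0687, log2 −1.14), a pseudocount of 0.1 (0.0514, log2 −1.31), the trend on gene span removed (0.0526, log2 −1.21) and no filter on low values (0.207). CYP71A13, an enzyme of camalexin synthesis, was 1.77-fold lower without passing (adjusted p = 0.0599). In the jasmonate list, 15 of 16 lay below 0 (median −0.35, by number −0.39 and −0.39), 2 fell and 9 did so adjusted over the list alone (camera adjusted p = 2.00e-08, adjusted p = 0.390 with an estimated correlation). VSP2, a vegetative storage protein gene, fell 2.36-fold from 159 ± 1.48 to 67.4 ± 11.5 FPKM (adjusted p = 0.0106), and LOX2, a lipoxygenase of jasmonate synthesis, fell 2.13-fold from 495 ± 4.77 to 232 ± 8.77 (adjusted p = 0.0133). JAZ9 (TIFY7, AT1G70700) was 1.62-fold lower (adjusted p = 0.0594). In the abscisic acid and cold list, 24 of 26 lay below 0 (median −0.30, by number −0.42 and −0.18), 2 fell and 5 did so adjusted over the list alone (camera adjusted p = 6.10e-07, adjusted p = 0.390 with an estimated correlation). RD29A (LTI78, AT5G52310) fell 2.83-fold (log2 −1.41, SE 0.13, adjusted p = 0.00341) and RD20 fell 2.06-fold (adjusted p = 0.0113). COR15B averaged 164 ± 44.2 and 85.2 ± 5.81 FPKM (adjusted p = 0.0797). With columns rescaled without rRNA loci CYP71A13, JAZ9 and COR15B passed (adjusted p = 0.00899, 0.00364 and 0.0155). CYP71A13 also passed without wild-type library 1 (adjusted p = 0.00350), COR15B without wild-type library 2 (0.00387), and CYP71A13 and JAZ9 without labelled mutant library 2 (0.0436 and 0.0218).

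**Figure D3:**
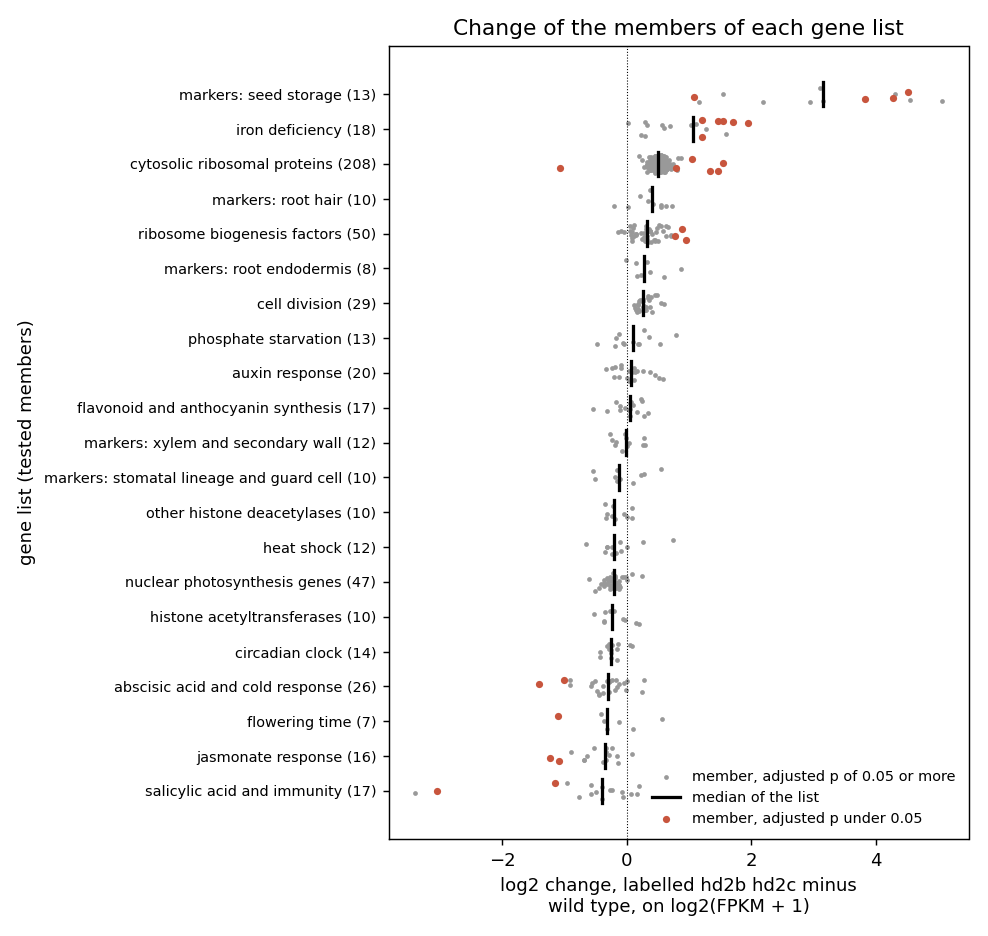
Log2 change of each tested member of 21 gene lists (points, red where adjusted p was under 0.05), with the median of each list as a black bar. The cytosolic ribosomal protein genes form a narrow band around 0.51, with RPL3B alone below 0.

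Seed storage markers had the largest shift of any list. All 13 lay above 0, with a median of 3.16 (3.28 and 4.01 by number), and the list held 4 risers, 8 adjusted over the list alone (camera adjusted p = 9.00e-18, adjusted p = 0.390 with an estimated correlation). Beside the 3 albumins, the oleosin gene OLEO4 rose 2.56-fold (adjusted p = 0.0311, but 0.0672 without labelled mutant library 2). The 3 albumins averaged 15.2 to 24.2 FPKM in the labelled mutants. The upper quartile of the list was a log2 change of 4.31, so members that were not called changed as much, and their levels are not given here.

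Photosynthesis and root marker genes shifted between the libraries numbered 1 and hardly between those numbered 2. Of 47 nuclear photosynthesis genes, 44 lay below 0 (median −0.21), but the median was −0.48 between libraries numbered 1 and 0.04 between those numbered 2. No member passed, over all genes or adjusted over the list alone. The camera adjusted p was 0.00275, and 0.428 without wild-type library 1 and 0.377 without labelled mutant library 1 (adjusted p = 0.729 with an estimated correlation). LHCB2.3, an antenna protein gene, averaged 1857 ± 51.1 and 1260 ± 426 FPKM (adjusted p = 0.269); PSAD2 (PSAD-2, AT1G03130) and LHCB4.2 had adjusted p of 0.296 and 0.356. These 3 genes passed with columns rescaled without rRNA loci (adjusted p = 0.0370, 0.0293 and 0.0486), PSAD2 also with quantile normalization (0.0471), and LHCB2.3 and PSAD2 without labelled mutant library 2 (0.0134 and 0.0471). Root hair genes had a median of 0.40 (9 of 10 above 0, by number 0.90 and −0.13, camera adjusted p = 0.0222). Root endodermis genes had a median of 0.28 (7 of 8 above 0, by number 0.71 and −0.08, camera adjusted p = 0.0293). Both had an adjusted p = 0.625 with an estimated correlation, and none of their members passed either way with all 4 libraries. Without labelled mutant library 1 the camera adjusted p were 0.683 and 0.661, and without wild-type library 1 they were 0.137 and 0.133. Examples are PRP3 (12.3 ± 3.72 against 19.6 ± 5.55 FPKM), XTH26 and EXPA18 (AT1G62980) of root hairs, and CASP4 (2.46-fold higher, adjusted p = 0.251), CASP2 and MYB36 of the endodermis. PRP3 passed without wild-type library 2 (adjusted p = 0.0295) and CASP4 without labelled mutant library 2 (0.0216).

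**Figure D4:**
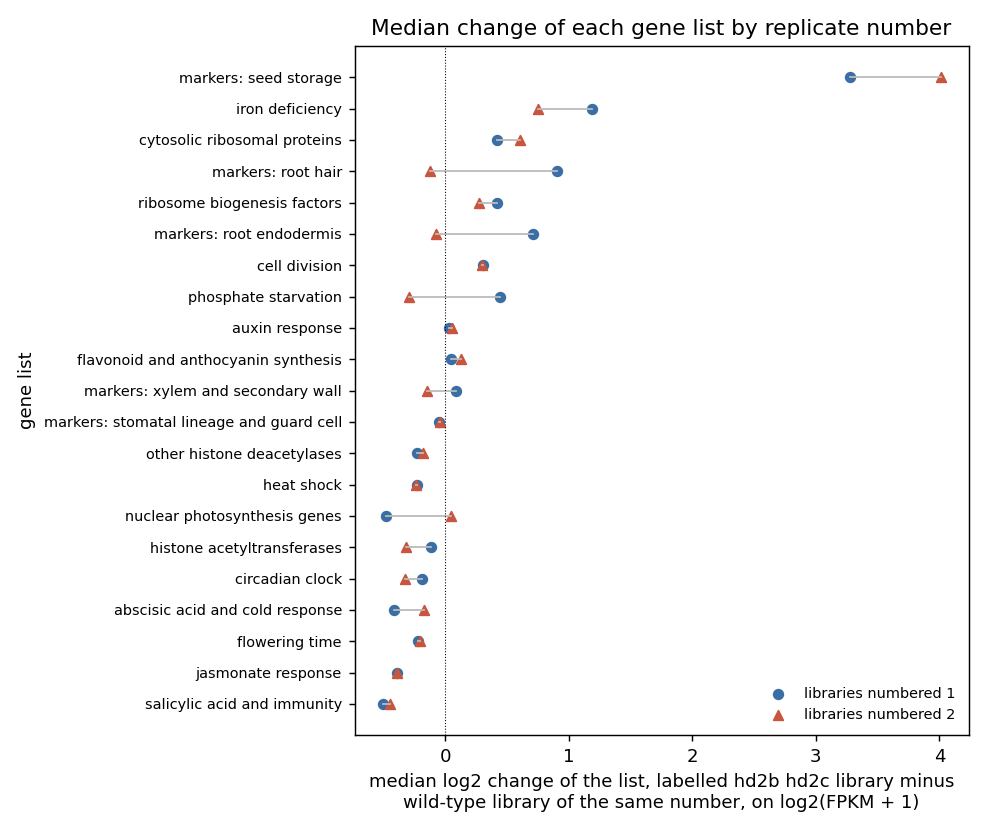
Median log2 change of 21 gene lists between the labelled mutant and the wild-type library numbered 1 (circles) and between those numbered 2 (triangles). Root hair, root endodermis, phosphate starvation, photosynthesis and xylem lists lie on opposite sides of 0 for the 2 numbers. Ribosomal protein, iron, seed storage, jasmonate and salicylic acid lists keep their side.

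Among flowering time genes, the floral repressor FLC fell 2.76-fold, from 5.00 ± 0.567 to 1.81 ± 0.506 FPKM (log2 −1.10, SE 0.18, adjusted p = 0.0350, but 0.0549 without labelled mutant library 1). The call also ended with the trend on gene span removed (adjusted p = 0.119, log2 −0.93) and with quantile normalization (0.0600, log2 −1.11). The floral inducer FT averaged 3.79 ± 0.150 and 6.06 ± 0.115 FPKM (adjusted p = 0.116), and MAF2 (AGL31, AT5G65050), a relative of FLC, 35.6 ± 2.09 and 26.5 ± 1.89 (adjusted p = 0.154). Of the 7 tested genes 1 fell; adjusted over the list alone 3 fell and 1 rose (median −0.32, by number −0.22 and −0.21), and the list did not pass (camera adjusted p = 0.0644). Circadian clock genes were lower as a list (12 of 14 below 0, median −0.25, by number −0.19 and −0.32, camera adjusted p = 0.00218, adjusted p = 0.390 with an estimated correlation), with none past the threshold singly and a median of −0.16 with the trend on gene span removed. FKF1 was 1.45-fold lower (adjusted p = 0.192), and PRR7 and RVE8 had adjusted p of 0.282 and 0.280. Other histone deacetylases had a median of −0.21 (7 of 10 below 0, by number −0.23 and −0.18, camera adjusted p = 0.0293, adjusted p = 0.625 with an estimated correlation) with no member past the threshold and a median of −0.12 with the trend on gene span removed. This list no longer passed with quantile normalization (adjusted p = 0.0549), without wild-type library 2 (0.128) or without labelled mutant library 1 (0.214). SRT2 averaged 14.4 and 11.1 FPKM (adjusted p = 0.202) and HDA8 (AT1G08460) 16.9 and 13.4 (0.231), and HDA14 was 1.28-fold lower. Histone acetyltransferases (median −0.23, by number −0.12 and −0.32, 8 of 10 below 0, camera adjusted p = 0.0644) and heat shock genes (median −0.21, by number −0.23 and −0.23, 9 of 12 below 0, camera adjusted p = 0.0721) did not pass.

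No shift past the threshold was found in the remaining lists. Phosphate starvation genes had a median of 0.10 (camera adjusted p = 0.317, by number 0.44 and −0.29). They were lower without wild-type library 1 (adjusted p = 0.00723) and higher without wild-type library 2 (adjusted p = 6.59e-06). Auxin response genes had a median of 0.07 (camera adjusted p = 0.379, by number 0.03 and 0.06), and flavonoid genes one of 0.06 (camera adjusted p = 0.715, by number 0.05 and 0.12). Medians were −0.13 for stomatal lineage and guard cell markers (camera adjusted p = 0.578, by number −0.05 and −0.04) and −0.02 for xylem and secondary wall markers (camera adjusted p = 0.715, by number 0.08 and −0.15).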

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

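The settings with the trend on gene span removed, alone or with the block, and the scaling of columns to equal sums were chosen only after the result was seen. Settings that need counts (size factors, library totals, count models and their weights) were not run because the values are FPKM.

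Loci higher and lower numbered 121 and 110. They numbered 19 and 20 with no filter on low values, 79 and 67 with a mean of at least 5 FPKM, 332 and 284 with columns rescaled without rRNA loci, 320 and 274 with equal column sums, and 31 and 26 at an adjusted p under 0.01. With the span trend removed 60 were higher. At least 2-fold higher and lower were 17 and 20 with no filter on low values, 34 and 41 with a mean of at least 5 FPKM, 18 and 26 with a pseudocount of 5, and 30 and 26 at an adjusted p under 0.01; 46 were higher with the span trend removed. Leaving out single libraries gave 146 to 390 loci higher, 107 to 160 lower, and 56 to 215 at least 2-fold higher. The share of higher loci moved from 52.4% to 75.4% without wild-type library 2. The prior degrees of freedom of the limma fit moved from 6.02 to 14.9 with the rRNA loci left out, to 14.1 with equal column sums and to 2.86 with no filter. Equal column sums kept every locus and gave nearly the same counts as leaving out rRNA loci. The gain in calls therefore came largely with the scaling of columns and not with the loss of rRNA loci. Other causes were not tested.

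Same-numbered libraries are not said to be paired, and with 2 pairs the r of 0.168 between their deviations cannot settle it. The libraries numbered 2 did share the fixed steps among low values, which the main fit leaves out of account. With the replicate number as a block 260 were higher and 172 lower, and HD2A (HDA3) passed at a log2 change of 0.88 (adjusted p = 0.0108). With this block PCNA1 (adjusted p = 0.0381), CYP71A13 (0.0179), JAZ9 (TIFY7, 0.0251) and U3D (0.0403) also passed, and NUC-L2 did not (0.0501). BHLH100 had a log2 change of 1.45 (adjusted p = 0.0814) with the span trend removed and a block.

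HD2A (HDA3) passed at 0.83 without rRNA loci, 0.83 with equal column sums and 0.86 with the span trend removed and a block; leaving out libraries gave 0.63 to 1.14. HD2D (HDT4) did not pass at 0.73 with no filter on low values or at 0.74 with a pseudocount of 0.1; leaving out libraries gave 0.64 to 0.83. HD2C ranged from −0.10 to 0.31, CASP5 from −0.30 to 0.29 and ESB1 from −0.025 to 0.35. CASP5 was 0.0021 with a pseudocount of 5.

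No list passed with an estimated inter-gene correlation. The adjusted p was 0.390 for abscisic acid and cold, cell division, clock, ribosomal protein, iron, jasmonate, seed storage, salicylic acid and snoRNA lists, 0.420 for ribosome biogenesis, 0.625 for root hair, endodermis and other histone deacetylases, and 0.729 for photosynthesis. With fry the salicylic acid list passed at 0.0222; the others had adjusted p of 0.0915 (jasmonate), 0.0920 (clock, iron, seed storage), 0.115 (ribosomal proteins, cell division), 0.186 (abscisic acid and cold, ribosome biogenesis), 0.326 (other histone deacetylases) and 0.529 (root hair, endodermis, photosynthesis, snoRNA). Both tests allow for correlated genes, which the preset 0.01 largely does not. Correlation alone does not account for the larger p. With an estimated correlation, camera also takes its few degrees of freedom from the residuals of the 4 libraries. With the preset it takes them from the number of genes. The salicylic acid list had an estimated correlation of −0.0495, yet its unadjusted camera p went from 2.08e-07 to 0.0305. The snoRNA list had −0.00927, and its unadjusted camera p went from 0.00204 to 0.0824. Both tests rest on 4 libraries, so failing them does not show that correlation explains a shift. Nor does passing with the preset exclude it.

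Heat shock genes passed with the span trend removed (adjusted p = 0.0109), also with a block (0.0114), and by ranks (0.0449), and flowering genes with no filter on low values (0.0155). Endodermis genes did not pass with a mean of at least 5 FPKM (0.0772), with the span trend removed (0.102) or with that and a block (0.133), root hair genes with the trend removed (0.0844, median 0.35 against 0.40) or with a block too (0.115), and other histone deacetylases with quantile normalization (0.0549), the trend removed (0.102) or a block too (0.159). Flavonoid genes changed direction with the trend removed (0.918) and stomatal genes with a mean of at least 5 FPKM (0.952), both far from passing. Leaving out single libraries moved the adjusted p of flavonoid genes from 0.0675 to 0.961, flowering 0.0362 to 0.194, heat shock 0.0480 to 0.449, histone acetyltransferases 0.0122 to 0.378, endodermis 1.49e-04 to 0.661, root hair 3.71e-05 to 0.683, stomatal 0.296 to 0.987, xylem 0.382 to 0.840, photosynthesis 5.71e-12 to 0.428, other histone deacetylases 0.0242 to 0.214 and phosphate 6.59e-06 to 0.402. Phosphate genes were lower without wild-type library 1 (0.00723). The cause was not tested.

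Of 33 named genes called outside the HD2 family, 12 kept the call in each alternative in which they were tested (low genes leave some of them), 10 lost it when a library was left out, and none of the 231 called loci changed sign. Without wild-type library 1, 71 named genes kept their reading, 7 were weaker, 2 stronger and 2 reversed.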

Other observations

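The symbol families, the runs of neighbouring genes, the starch genes, the lists of DNA damage, dry seed and lipid use genes, and the removal of the span trend were chosen only after the result was seen. Genes named here outside the lists were also chosen after their values were seen.

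Ribosomal protein genes were higher, and length, scaling and shared reads were tested as technical explanations. The list median was 0.51, against at most 0.11 in 1000 random lists matched on gene span and mean level, both without subtraction. Random genes were drawn singly, so their narrow spread does not allow for correlation within the list (estimated at 0.521). After the trend on gene span was subtracted the list median was 0.41. With quantile normalization it was 0.34. With copies summed over 80 proteins the median was 0.51, and all 80 lay above 0, RPL3 among them at 0.43. These tests leave a rise, but they do not separate genotype from a difference between the cultures.

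Seed storage genes were higher, which could come from ungerminated seeds or from slower development. A list of late embryogenesis and oil body genes of dry seeds had a median of 0.79 (11 tested, by replicate number 0.62 and 0.82, quartiles 0.30 and 1.04), against 3.16 for storage genes. Of these 11, 9 lay above 0 and AT3G17520 rose (adjusted p = 0.0348), with a camera p of 3.51e-05 and 0.130 with an estimated correlation. A list of genes of lipid use after germination had a median of −0.0562 (by number −0.02 and −0.05), with 5 of 14 above 0. The quartiles of the lipid use list were −0.14 and 0.06, so these genes were not higher as a group. Among the 5 above 0, ICL (log2 0.557, adjusted p = 0.235) and MLS (log2 0.237, adjusted p = 0.53) were the highest, and neither passed. ICL stood at 9.63 and 13.5 FPKM in wild type and at 14.6 and 20.4 in the labelled mutants. A rise of the whole list from slower development was therefore not seen, but slower development without such a rise is not excluded. The dry seed list does not decide on ungerminated seeds, since it was higher but by less than the storage genes on the log2(FPKM + 1) scale. That scale understates changes of weakly expressed genes, and only 11 of the 17 dry seed genes passed the filter on low values. Other explanations were not tested.

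NAC044 was among the largest rises, and a DNA damage response list tested whether other such genes changed. The median was 0.35 (by number 0.32 and 0.36), 13 of 15 lay above 0, and NAC103 (log2 1.34, adjusted p = 0.0103) and GMI1 (log2 0.93, adjusted p = 0.0484) rose. The camera p was 7.51e-05, and 0.103 with an estimated correlation.

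Starch enzyme genes were among the lower genes: SEX1 (log2 −0.83), PWD (AT5G26570, −0.68), LDA (−0.77), ISA3 (−0.76) and SBE2.1 (−0.74) fell. Of the other 23 starch metabolism genes 22 lay below 0 (median −0.32, by number −0.46 and −0.29), and their median was −0.24 after the trend on gene span was subtracted. The camera p was 8.20e-10 without subtraction and 9.14e-07 with the trend subtracted. With an estimated correlation, and without subtraction, the p was 0.111.

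Segments of another background linked to the mutated loci were tested in windows of 200 neighbouring tested genes, which replaced the planned windows of fixed length because coordinates were not used. The windows of HD2B and HD2C held 2 called genes each, HD2B itself among them, and the smaller p was 0.677. None of 103 windows passed (smallest adjusted p = 0.910).

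Called genes lay side by side, in the order of tested loci, in 10 pairs, all 10 with both genes in the same direction. In 1000 random orders the median was 3 and the highest 9. The pairs are not all separate, since AT2G41580 was paired both with AT2G41570 and with AT2G41590. These loci stood at 1.81 to 3.07 FPKM in wild type and at most 0.0381 in the labelled mutants. The pairs included WAK1 and WAK3 (lower), RLP40 and RLP41 (lower), and IMA1 and IMA2, bHLH38 and bHLH39, and SESA1 and SESA2 (higher). Several are tandem copies, and reads shared between copies were not tested.

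Of 199 symbol families with at least 8 tested genes, 27 passed, 14 passed with the span trend removed (13 of them in both), and none with an estimated correlation (smallest adjusted p = 0.965). XTH genes, which remodel cell walls, lay above 0 in 23 of 25 (median 0.41, by replicate number 0.39 and 0.16), and none was called. RLP receptor genes lay above 0 in 8 of 35 (median −0.16, by number −0.23 and −0.23), and 3 fell. Other genes that fell, picked by their values and not tested as a group, were WAK1 (log2 −1.70), LURP1 (−2.72), PBS3 (−1.53), ACD6 (−1.51), WRKY46 (−0.88) and AIG1 (−1.76). The WRKY family did not fall: 32 of 53 lay above 0 (median 0.13, by replicate number 0.30 and −0.07), and 2 members were called lower.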
